A study of Mus musculus with 24 samples.

How the data were processed

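RNA-seq was measured in 24 libraries from embryos of C57BL/6J mice at embryonic day 10.5. Per the labels' protocols, embryos received an injection into the heart of either a control antibody (anti-human IgG) or an antibody against the Notch ligand Dll4, and were then kept for 5 h at 37 °C and 5% CO2 in medium with 5 µg/ml of the same antibody, 10 ng/ml IL-3 and 10 µM hydrocortisone. Per the labels' protocols, the tissue was digested with collagenase, cells were sorted by flow cytometry, and polyA RNA was turned into cDNA that was amplified by long-distance PCR before library preparation and sequencing on an Illumina HiSeq instrument. The sample titles give 3 sorted populations, all CD31+, which are called here Kit+ CD45-, Kit- CD41+ CD45- and Kit+ CD45+. Each population and antibody has 4 replicates, so there are 6 groups of 4 libraries.

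Per the submitters' processing notes, CASAVA 1.4, FastQC, STAR, HTSeq and DESeq2 were used with genome build mm10; which tool did which step and the release of the gene annotation are not given in the sources used here. The deposited count table holds raw reads per gene, without normalization, for 29716 genes. The deposited log2 table holds values normalized by the authors for 30202 genes, 486 of them not in the count table, and 1 of its library columns belongs to no listed sample and was not used here. For the 24 listed libraries the log2 values equal log2(count / size factor + 1), to within 5.3e-14, with size factors between 0.4544 and 1.56. All tests used the counts. Gene positions are those of the authors' table on mm10, and equal those of GENCODE M21 for the 26354 genes whose versioned identifier is in that release.

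Library totals ran from 8718351 to 11379830 counts, and 18063 to 21093 genes had at least 1 count. Amplified reads carry no molecular identifiers here and are not independent molecules, so every floor given covers counting error only. The floor is 3 counts per library: a fold against a group with no counts in any library is given as a lower bound against it. CPM in the text are counts scaled to a common library total with TMM factors, unless stated otherwise, and each mean is given with its SD over 4 libraries.

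The main test was edgeR 4.0.16 (R 4.3.3) with TMM normalization, the default filterByExpr filter by group, robust dispersion estimation and the quasi-likelihood F-test, with 1 coefficient per group over all 24 libraries and 18 residual degrees of freedom. It tested 15618 genes, 13166 of them protein-coding; the biological coefficient of variation was 0.343. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Fold changes are log2 values, and their standard error (SE) was taken from the fold change and the F statistic. Comparisons were anti-Dll4 against IgG in each of the 3 populations, the mean of these 3 effects, the difference of the effect between populations (an F-test with 2 degrees of freedom), and the 3 pairs of populations under IgG. The labels do not state how many embryos stand behind a library, so the p-values measure the spread between these samples.

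A total of 26 gene lists with 566 genes, 555 of them in the count table, was fixed before the data were examined, as were the comparisons, the tests and most alternatives: Notch pathway components, Notch target genes, arterial, venous and pan-endothelium, haematopoietic transcription factors, HSC and progenitor genes, erythroid, megakaryocyte and platelet, granulocyte-monocyte progenitor, macrophage, mast cell and basophil, lymphoid, mesenchyme and smooth muscle, epithelium with liver bud and neural genes, S phase, G2/M, TGF-beta and BMP signalling, interferon response, NF-kB and TNF response, immediate early and dissociation stress genes, hypoxia and glycolysis, oxidative phosphorylation, cholesterol synthesis, adhesion and migration, and p53 targets. The mast cell list kept fewer than 5 tested members and was not tested. The other 25 were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists within each comparison; camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction, stand beside it. A list score is the mean log2 CPM of a list in 1 library. Scores and library measures were compared by exact permutation tests of both directions over the 70 arrangements of 4 against 4 libraries, whose smallest p is 0.0286, adjusted by Benjamini-Hochberg within each family. For values averaged over the populations, and for splits of the average and of the difference between populations, the 3 libraries of a set were moved together, a choice made after the data were seen. A list of 15 germ cell genes was written after the data were seen.

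Genes named in the text follow a rule: among genes past the threshold with at least 5 CPM in the higher group and a symbol that is not a predicted model, the 10 with the smallest p in each direction; where none passed, the 5 with the smallest p in each direction; always Pecam1, Kit, Itga2b, Ptprc, Dll4, Notch1, Notch4, Hes1, Hey1, Hey2, Nrarp, Gfi1, Gfi1b, Runx1, Gata2 and Cdh5; and the 4 members of each list with the smallest p. From these the text names those that carry a comparison. Results for 3 single genes are not reported here. A single gene outside the rule, 4931440F15Rik, and the germ cell and sex-linked genes were chosen after their values were seen.

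Alternatives were RLE and upper-quartile size factors, DESeq2 1.42.0 with its own factors and filtering, limma-voom with sample weights, voom with the set of 3 libraries that share a number in their descriptions as a random effect, no low-count filter, a filter of at least 10 counts in 4 libraries of a group, a replicate block, a test against a fold of 1.5, only the groups compared, and leaving out each library or each replicate number in turn. Added after seeing the data were 4 more: globin genes removed, globin level as a covariate within each population, and the fit without the libraries of set 1 or of set 2. The fit with the set as a random effect used voom without sample weights. It differs from the main test in the tool too, so its changes cannot be put down to the set alone.

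The steps were tested on simulated counts with the library sizes of these data, and with 67, 67 and 66 genes changed 1.5-, 2- and 4-fold. Their means and dispersions were fitted with 1 coefficient per population, both antibodies pooled. Any real effect of the antibody is thus part of the simulated spread. In the Kit+ CD45- comparison, edgeR called 13.4% of genes changed 1.5-fold, 41.8% of those changed 2-fold and 83.3% of those changed 4-fold, among 15134 tested, and 7 of its 99 calls were genes left unchanged. DESeq2 called 17.9%, 55.2% and 89.4% there among 14404 tested, and 22 of its 130 calls were unchanged genes. For 2-fold changes edgeR called 37.3% in Kit- CD41+ CD45- cells (15218 tested), 29.9% in Kit+ CD45+ cells (15204 tested), 76.1% for the mean effect (15155 tested) and 10.4% for the difference between populations (15134 tested). With the pan-endothelium list lowered 1.5-fold in simulated Kit+ CD45- libraries, camera gave that list an adjusted p of 2.83e-05, or 0.00082 with an estimated correlation, and called none of the 20 lists that share no member with it. The simulated genes varied independently of each other, so this says nothing about false calls of lists whose genes vary together. Changed genes were drawn only from those above a minimum mean count, so the percentages do not cover genes with lower counts.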

Results

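The series holds 24 RNA-seq libraries of CD31+ cells sorted from mouse embryos after 5 h under a control antibody (IgG) or an antibody against Dll4, a ligand of the Notch receptors on endothelium. Its title concerns the role of Dll4 in the entry of hemogenic cells into clusters of the aorta and in the output of hematopoietic stem cells. Its design names genes that differ with the antibody in 3 sorted populations. These are Kit+ CD45- cells, Kit- CD41+ CD45- cells and Kit+ CD45+ cells, with 4 libraries per population and antibody. Totals per library were 8718351 to 10642459 counts in Kit+ CD45- cells, 9723206 to 11379830 in Kit- CD41+ CD45- cells and 8973458 to 11115548 in Kit+ CD45+ cells. Levels below are TMM-scaled CPM from the deposited raw counts, as means ± SD over 4 libraries (n = 4). Fold changes are log2 values with their standard error (SE) from the edgeR quasi-likelihood fit to all 24 libraries.

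The transcripts of the 4 sorting markers followed the gates. Under IgG, Kit (chromosome 5, 75574916 to 75656722, mm10, ENSMUSG00000005672.12) stood at 37.9 ± 4.72 CPM in Kit+ CD45- cells, 60.8 ± 16.9 in Kit+ CD45+ cells and 3.84 ± 1.47 in Kit- CD41+ CD45- cells. Itga2b, which encodes CD41 (chromosome 11, 102453297 to 102470122, ENSMUSG00000034664.13), stood at 540 ± 162 CPM in Kit- CD41+ CD45- cells, 58.6 ± 31.3 in Kit+ CD45- cells and 14.6 ± 2.89 in Kit+ CD45+ cells. Ptprc, which encodes CD45 (chromosome 1, 138062861 to 138175708, ENSMUSG00000026395.16), stood at 82.3 ± 33 CPM in Kit+ CD45+ cells and at 0.811 ± 0.785 in Kit+ CD45- cells. No library of Kit- CD41+ CD45- cells under IgG had a Ptprc count. The level in Kit+ CD45+ cells is at least 285-fold higher, against a floor of 3 counts per library. Pecam1, which encodes CD31 (chromosome 11, 106654217 to 106750628, ENSMUSG00000020717.19), was measured in all 3 populations, at 155 ± 67 CPM in Kit+ CD45- cells and 250 ± 52.6 in Kit+ CD45+ cells. Against Kit- CD41+ CD45- cells it was higher by 1.21 (SE 0.28) and 1.9 (SE 0.28).

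**Figure D1:**
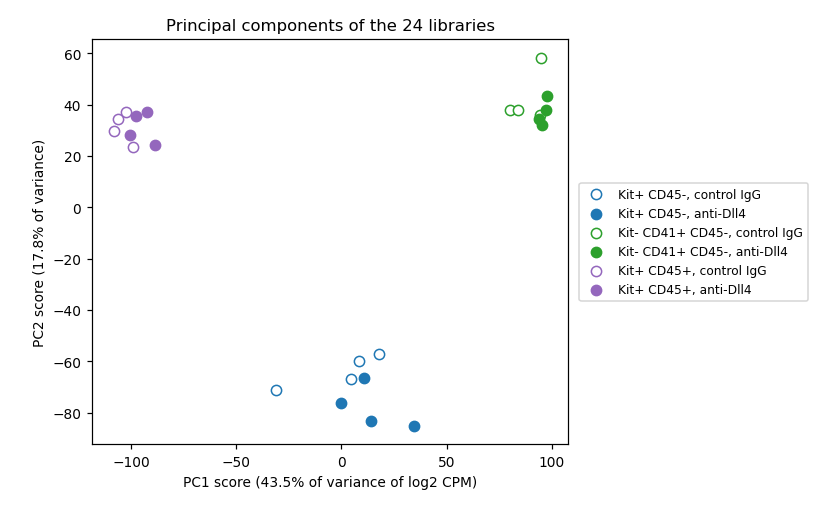
Principal components 1 and 2 of log2 CPM (scores, 43.5% and 17.8% of the variance), 1 point per library; colour gives the population, open points IgG and filled points anti-Dll4. The 3 populations form separate groups, with component 1 between 80 and 97.7 in Kit- CD41+ CD45- cells and between -108.4 and -88.9 in Kit+ CD45+ cells.

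Red blood cell transcripts differed widely between populations. Globin genes took 26.9 ± 7.21% of the counts in Kit+ CD45- cells under IgG and 35.4 ± 11.2% under anti-Dll4 (exact permutation p = 0.257, n = 4). In Kit- CD41+ CD45- cells the share was 6.63 ± 2.79% and 11.7 ± 2.72% (exact permutation p = 0.0571, n = 4), and in Kit+ CD45+ cells it was 0.015 ± 0.0061% and 0.0148 ± 0.00604%. Y-linked transcripts came from the 3 libraries of replicate 1 under anti-Dll4, where Ddx3y had 523, 952 and 1244 counts and Xist at most 5. The other 21 libraries had at least 1455 Xist counts and at most 15 from Y-linked genes. Kit+ CD45- IgG replicate 1 stood apart in its group, with the lowest globin share (16.85%). Its Cdh5 level before TMM scaling was 51.6 CPM, against 21.1 to 22.9 in the other 3.

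The 1st comparison of populations asked what separates Kit+ CD45- cells from Kit- CD41+ CD45- cells under the control antibody. Kit+ CD45- cells carried an endothelial programme with red cell transcripts, and Kit- CD41+ CD45- cells a platelet one. In the pan-endothelium list 23 of 28 members were higher in Kit+ CD45- cells and 1 lower, both over all genes tested and adjusted over the list alone, with a median log2 fold change of 3.51. Ramp2, a co-receptor for adrenomedullin, stood at 222 ± 57.8 CPM against 6.69 ± 4.07 (log2 fold change 5.05, SE 0.38, adjusted p = 2.01e-09). Cdh5, the cadherin of endothelial junctions (chromosome 8, 104101625 to 104144511, ENSMUSG00000031871.9), stood at 31 ± 10.6 against 0.572 ± 0.605. Flt4, a receptor for Vegfc, stood at 12.8 ± 3.15 CPM against 0.0214 ± 0.0428, and Dll4 itself at 12.1 ± 7.24 against 0.202 ± 0.341 (adjusted p = 2.05e-05). Arterial genes were higher for 15 of 22 members (16 adjusted over the list alone) and venous genes for 8 of 10 (8 adjusted over the list alone). Camera placed all 3 endothelial lists above other genes, and each held at an adjusted p = 0.0309 with an estimated correlation.

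All 23 megakaryocyte and platelet genes were lower in Kit+ CD45- cells, over all genes and adjusted over the list alone, with a median of -3.15 (camera adjusted p = 4.88e-26, and adjusted p = 0.00299 with an estimated correlation). F2rl2, a thrombin-binding receptor of platelets (chromosome 13, 95696853 to 95702739, ENSMUSG00000021675.4), stood at 290 ± 104 CPM against 2980 ± 245. Clec1b, a platelet receptor for podoplanin, stood at 165 ± 24.4 against 1050 ± 137. Among the genes with the smallest p were Lims1 (493 ± 108 against 2370 ± 213 CPM) and Tln1 (70.7 ± 12.2 against 323 ± 8.71), which with Ilk link integrins to actin. Runx1, the transcription factor that drives blood cells out of endothelium, was lower in Kit+ CD45- cells (38.2 ± 15.2 against 148 ± 16.6 CPM, log2 fold change -1.96, SE 0.24), and so was its target Gfi1b (-1.52, SE 0.28). These values do not tell a difference in that step from one in platelet cells, whose transcripts are high in Kit- CD41+ CD45- cells. Cholesterol synthesis genes were lower for 13 of 22 members (14 adjusted over the list alone). The list had a camera adjusted p = 1.42e-05 and an adjusted p = 0.101 with an estimated correlation. Erythroid genes were higher for 21 of 24 (21 higher and 1 lower adjusted over the list alone), such as Slc4a1, the red cell anion exchanger (3.12, SE 0.37), beside the higher globin share of these cells. That list had a camera adjusted p = 1.72e-10 and an adjusted p = 0.185 with an estimated correlation. The Notch targets Hes1 (1.84, SE 0.3) and Hes7 (-2.77, SE 0.41) went opposite ways, and their list had an adjusted p = 0.236 with an estimated correlation. The S phase, G2/M, TGF-beta and adhesion lists passed camera at the preset correlation too, and had adjusted p from 0.238 to 0.335 with an estimated correlation. In all, 4357 of 15618 genes passed the threshold, 2194 higher and 2163 lower in Kit+ CD45- cells, and 2802 of them differed by more than 2-fold. A test against a fold of 1.5 called 2219. Upper-quartile scaling moved the median log2 fold change of all genes from 0.056 to 0.159 and the calls to 2676 higher and 1844 lower. It did not turn the direction of a gene named here.

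The 2nd comparison asked what separates Kit+ CD45+ cells from Kit+ CD45- cells under IgG. Kit+ CD45+ cells carried leukocyte transcripts and few red cell ones. In the macrophage list 18 of 19 members were higher, over all genes and adjusted over the list alone (median 8.74, camera adjusted p = 1.39e-24, and adjusted p = 0.0207 with an estimated correlation). Cd68, a lysosomal protein of macrophages, stood at 149 ± 75.8 CPM against 1.98 ± 0.707. The chemokine Ccl3 (chromosome 11, 83647844 to 83649355, ENSMUSG00000000982.5) stood at 354 ± 159 against 0.804 ± 1.17. C1qc, at 0 counts in Kit+ CD45- cells under IgG, was at least 784-fold higher. Granulocyte-monocyte genes were higher for 9 of 16 (9 adjusted over the list alone), such as Mpo, the peroxidase of neutrophil granules (240 ± 145 against 8.76 ± 1.78 CPM). Spi1, the myeloid transcription factor PU.1, was higher by 2.96 (SE 0.26). The granulocyte-monocyte list, the lymphoid list (4 of 9 higher, 4 adjusted over the list alone) and the NF-kB and TNF list (17 of 23 higher, 17 adjusted over the list alone) held with an estimated correlation, at an adjusted p = 0.035, adjusted p = 0.0439 and adjusted p = 0.00532. Kit+ CD45+ IgG replicate 1 had lower scores than the other IgG libraries of these cells. They were 2.67 for macrophage genes (5.84 to 6.51 in the others), 2.43 for granulocyte-monocyte genes (3.81 to 4.48) and 3.26 for NF-kB genes (4.25 to 4.87). The highest macrophage score in Kit+ CD45- cells under IgG was -0.35. Runx1 was higher in Kit+ CD45+ cells than in Kit+ CD45- cells, by 1.2 (SE 0.24).

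All 24 erythroid genes were lower in Kit+ CD45+ cells, over all genes and adjusted over the list alone, with a median of -8.85 (adjusted p = 0.000118 with an estimated correlation). Alas2, the first enzyme of heme synthesis in red cells (chromosome X, 150547375 to 150570638, ENSMUSG00000025270.13), stood at 0.601 ± 0.367 CPM against 1760 ± 537. The embryonic globin Hbb-y stood at 59.9 ± 37.7 against 137000 ± 52800. Megakaryocyte and platelet genes were lower for 18 of 23 and higher for 2 (18 and 2 adjusted over the list alone; adjusted p = 0.0354 with an estimated correlation), among them F2rl2 (6.02 ± 3.12 against 290 ± 104 CPM). The proliferation marker Mki67 (-1.25, SE 0.19) was lower, while the G2/M list (6 of 27 lower, 6 adjusted over the list alone) had an adjusted p = 0.383 with an estimated correlation. Of the other lists past camera's threshold there, pan-endothelium, HSC and progenitor, interferon, immediate early, hypoxia and adhesion genes had higher mean scores in Kit+ CD45+ cells. Mesenchyme, epithelium, S phase and oxidative phosphorylation genes had lower ones. The pan-endothelium score was 6.26 ± 0.3 in Kit+ CD45+ cells and 5.75 ± 0.47 in Kit+ CD45- cells under IgG. With an estimated correlation the adjusted p of all these lists ran from 0.105 to 0.522. In all, 2998 genes passed the threshold, 1564 higher and 1434 lower, 1837 by more than 2-fold, and 1303 passed a test against a fold of 1.5. The higher genes were 52.2% of the calls under TMM and 41.8% under upper-quartile scaling, so neither direction led under both. The count was 1551 without replicate 2 of every group, 1756 without replicate 3 and 1955 without replicate 4.

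The 3rd comparison set Kit+ CD45+ cells against Kit- CD41+ CD45- cells under IgG, and had the highest count of the 3 pairs. Megakaryocyte and platelet genes were lower in Kit+ CD45+ cells for 21 of 23 (21 adjusted over the list alone; median -6.43, adjusted p = 0.00406 with an estimated correlation) and erythroid genes for 24 of 24 (24 adjusted over the list alone; adjusted p = 0.0196 with an estimated correlation). F2rl2 stood at 6.02 ± 3.12 CPM against 2980 ± 245 (log2 fold change -8.96, SE 0.47, adjusted p = 4.16e-12). Gfi1b stood at 40.9 ± 16.9 against 548 ± 88.4. Pan-endothelial genes were higher in Kit+ CD45+ cells for 24 of 28 and lower for 2 (26 and 2 adjusted over the list alone; adjusted p = 0.0252 with an estimated correlation). The endothelial transcription factor Sox18 stood at 125 ± 32.5 CPM against 1.23 ± 1.11. Lcp1, a leukocyte actin-bundling protein (chromosome 14, 75131101 to 75230842, ENSMUSG00000021998.16), stood at 260 ± 50.8 against 5.65 ± 1.76. Upp1, a uridine phosphorylase, stood at 175 ± 41.8 against 3.85 ± 1.48. Cholesterol synthesis genes were lower for 14 of 22 (15 adjusted over the list alone; adjusted p = 0.0366 with an estimated correlation), such as the sterol carrier Stard4 (-1.75, SE 0.17). The venous, granulocyte-monocyte, lymphoid, NF-kB and adhesion lists were higher with both correlations, at adjusted p from 0.0252 to 0.0366 with an estimated correlation. The Notch pathway, arterial, macrophage, mesenchyme, TGF-beta and immediate early lists passed at the preset correlation alone, with adjusted p from 0.0642 to 0.336 with an estimated correlation. In all, 5815 genes passed, 3082 higher and 2733 lower, 3928 by more than 2-fold, and 3437 passed a test against a fold of 1.5.

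The main question of the series was what blocking Dll4 changes, here in Kit+ CD45- cells. By camera at the preset correlation, endothelial, platelet, adhesion and TGF-beta lists were lower under anti-Dll4 and the erythroid list higher. None of the 25 lists passed with an estimated correlation, and no single gene passed the threshold over all genes in edgeR. In the pan-endothelium list 27 of 28 members were lower, with a median log2 fold change of -0.86 (camera adjusted p = 2.99e-10, and adjusted p = 0.0991 with an estimated correlation). Of these, 0 passed over all genes and 6 adjusted over the list alone. Pecam1 stood at 85.8 ± 31.9 CPM against 155 ± 67 under IgG; its log2 fold change of -0.85 was -0.51 without IgG replicate 1 and -0.38 with globin level as a covariate. Flt1, a receptor for Vegfa, stood at 77.6 ± 21.7 against 164 ± 58.6, and Cdh5 at 16.2 ± 4.32 against 31 ± 10.6. Arterial genes were lower for 21 of 22 (median -0.9, 1 adjusted over the list alone; camera adjusted p = 6.09e-06, and adjusted p = 0.0991 with an estimated correlation). Efnb2, an arterial Notch target, stood at 7.28 ± 3.49 against 17 ± 8.34 CPM. IgG replicate 1 stood apart in it, and its log2 fold change of -1.22 was -0.82 without that library and -0.78 with the globin covariate. All 10 venous genes were lower (median -0.91, 0 adjusted over the list alone; camera adjusted p = 0.00179, and adjusted p = 0.0991 with an estimated correlation). The Notch target list (13 of 17 lower, median -0.77, 2 adjusted over the list alone) and the Notch pathway list (22 of 26 lower, median -0.43, 0 adjusted over the list alone) had camera adjusted p = 0.000991 and 0.0116, and each an adjusted p = 0.0991 with an estimated correlation. These lists share members, so their calls are not separate results. Dll4, Efnb2, Hey1 and Hey2 are Notch targets and arterial genes here, and Notch1, Notch4, Jag1 and Jag2 are pathway and arterial genes. Pecam1, Cdh5, Esam and Icam2 are in the adhesion and pan-endothelium lists. Hes1, the transcriptional repressor switched on by Notch (chromosome 16, 30064384 to 30067796, ENSMUSG00000022528.7), stood at 29.2 ± 2.65 CPM against 63.8 ± 21 (log2 fold change -1.13, SE 0.3, adjusted p = 0.195). It was lower in each anti-Dll4 library than in any IgG library.

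All 23 megakaryocyte and platelet genes were lower under anti-Dll4 in Kit+ CD45- cells (median -0.89, camera adjusted p = 9.74e-13, and adjusted p = 0.0991 with an estimated correlation). Of these, 0 passed over all genes and 15 adjusted over the list alone. The list score did not part the antibodies: IgG replicate 1 was at 4.75, as low as the lowest anti-Dll4 library (4.75 to 5.31), and the other 3 IgG libraries were at 6.02 to 6.73 (exact permutation p = 0.114, adjusted 0.259). Gp6, the platelet collagen receptor (chromosome 7, 4363965 to 4397744, ENSMUSG00000078810.4), stood at 2.91 ± 1.26 CPM against 17 ± 11.1 and Clec1b at 94.3 ± 23.2 against 165 ± 24.4 (both at an adjusted p of 0.12). Adhesion genes (25 of 28 lower, 4 adjusted over the list alone), TGF-beta and BMP genes (20 of 22 lower; 5 lower and 1 higher adjusted over the list alone), NF-kB and TNF genes (21 of 23 lower, 2 adjusted over the list alone) and HSC and progenitor genes (22 of 28 lower, 1 adjusted over the list alone) passed camera. Each had an adjusted p = 0.0991 with an estimated correlation. Examples are Smad7, an inhibitor of TGF-beta signalling (3.98 ± 1.41 against 10.7 ± 5.65 CPM), the TGF-beta receptor Tgfbr2 (6.9 ± 1 against 15.7 ± 7.18) and the adhesion molecule Icam1 (11.8 ± 5.79 against 33.5 ± 21.4). The log2 fold change of Icam1 went from -1.49 to -0.99 without IgG replicate 1 and to -0.82 with the globin covariate, which also took Smad7 from -1.42 to -0.92. Immediate early genes were lower for 20 of 26 (0 adjusted over the list alone; camera adjusted p = 0.0116, and adjusted p = 0.387 with an estimated correlation). All 24 erythroid genes had higher values (median 0.55, 0 adjusted over the list alone; camera adjusted p = 1.96e-06, and adjusted p = 0.247 with an estimated correlation), beside the globin share given above. The median was 0.34 without IgG replicate 1 and 0.31 without anti-Dll4 replicate 4, and the list score had an exact permutation p of 0.286. Values were higher also for 25 of 27 oxidative phosphorylation genes (0 adjusted over the list alone; adjusted p = 0.247 with an estimated correlation) and 22 of 27 G2/M genes (0 adjusted over the list alone; adjusted p = 0.252 with an estimated correlation). The gene with the smallest p among lower ones encodes the actin-severing protein gelsolin (Gsn, chromosome 2, 35256380 to 35307892, ENSMUSG00000026879.14; 3.73 ± 2.44 against 22 ± 6.62 CPM, log2 fold change -2.5, SE 0.43, adjusted p = 0.0562). Among higher ones with at least 5 CPM it was Sepsecs, an enzyme of selenocysteine synthesis (11.4 ± 1.73 against 5.52 ± 1.45 CPM, adjusted p = 0.193).

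Fry called 10 of these lists in Kit+ CD45- cells, all lower (adjusted p from 0.0173 to 0.0323), and not the erythroid, oxidative phosphorylation, G2/M or immediate early lists (0.167 to 0.201). Lists without a camera call were haematopoietic transcription factors (adjusted p = 0.37), granulocyte-monocyte and macrophage genes (both 0.841), lymphoid (0.108), mesenchyme (0.125), epithelium (0.315), S phase (0.145), interferon (0.513), hypoxia (0.545), cholesterol (0.268) and p53 targets (0.354). Kit, Gfi1, Gfi1b, Runx1 and Gata2 had log2 fold changes between -0.26 and 0.11, with a smallest unadjusted p of 0.396. The edgeR count of 0 stands beside 1733 genes at an unadjusted p under 0.05 (1198 lower), where 781 would be 5% of those tested. DESeq2 called 75 genes (73 lower), and limma-voom with weights 0. The count was 8 without IgG replicate 1, 12 without IgG replicate 2, 23 without anti-Dll4 replicate 1 and 67 without replicate 1 of every group, all of them lower. Without IgG replicate 1 the pan-endothelium median was -0.47, the venous one -0.6 and the Notch pathway one -0.27 (adjusted p = 0.0801). Without anti-Dll4 replicate 2 the Notch target median was -0.51. The immediate early call ended without IgG replicate 1 (0.109), without IgG replicate 4 (0.053) and without anti-Dll4 replicate 1 (0.242).

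**Figure D2:**
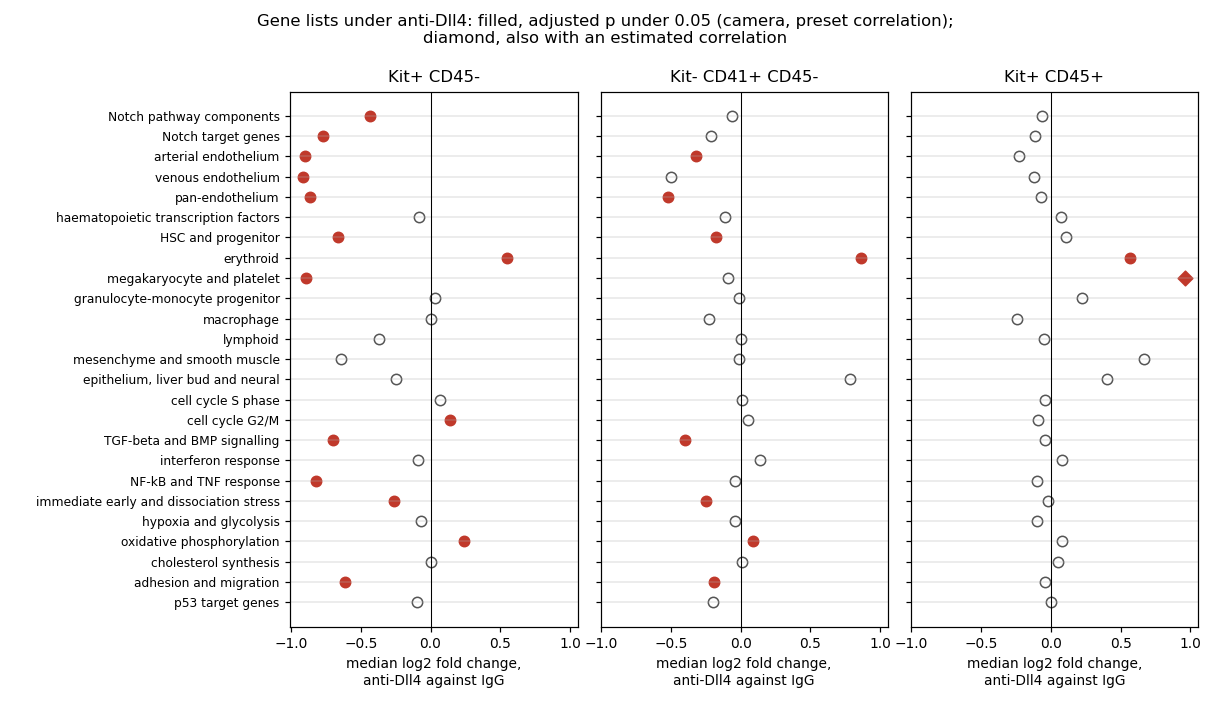
Median log2 fold change (x axis, anti-Dll4 against IgG) of the tested members of 25 gene lists (y axis) in the 3 populations; filled points have a camera adjusted p under 0.05 at the preset correlation, and the diamond also with an estimated correlation. In Kit+ CD45- cells 11 lists passed below 0 and 3 above, in Kit- CD41+ CD45- cells 6 and 2, and in Kit+ CD45+ cells 2 above.

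In Kit- CD41+ CD45- cells, anti-Dll4 went with higher red cell transcripts and lower Hes1, again without a gene past the threshold. Erythroid genes had higher values for 23 of 24 members (median 0.86, 0 past over all genes and 2 adjusted over the list alone; camera adjusted p = 1.45e-23, and adjusted p = 0.0869 with an estimated correlation), beside a globin share of 11.7 ± 2.72% against 6.63 ± 2.79%. Slc4a1 stood at 20.3 ± 6.96 CPM against 7.36 ± 2.68 and Tspan33, a tetraspanin of red cell precursors, at 44.8 ± 15 against 17.9 ± 3.68 (both at an adjusted p of 0.806). Their log2 fold changes of 1.47 and 1.33 ran from 0.8 to 1.8 and from 0.71 to 1.53 over the alternatives. Hes1 stood at 7.22 ± 1.51 CPM against 17.9 ± 10 (log2 fold change -1.31, SE 0.32, adjusted p = 0.806), though IgG replicate 1 (6.16 CPM) lay within the range of the anti-Dll4 libraries. Pan-endothelial genes were lower for 26 of 28 (median -0.52, 0 adjusted over the list alone; camera adjusted p = 6.49e-05, and adjusted p = 0.503 with an estimated correlation), a call that ended without IgG replicate 2 (0.392, median -0.19). Without IgG replicate 1 the median was -0.79. The arterial, HSC and progenitor, TGF-beta, immediate early and adhesion lists were lower by camera too, each with an adjusted p = 0.503 with an estimated correlation. Oxidative phosphorylation was higher (adjusted p = 0.715 with an estimated correlation). Without IgG replicate 3 the arterial, HSC and TGF-beta calls ended (each 0.242), and so did oxidative phosphorylation (0.111). Without anti-Dll4 replicate 1 the HSC, immediate early and adhesion calls ended (each 0.0604), with arterial (0.0834) and oxidative phosphorylation (0.0846). Without IgG replicate 2 the arterial (0.392), HSC (0.137), adhesion (0.0533) and oxidative phosphorylation (0.0875) calls ended. Anti-Dll4 replicate 4 ended arterial (0.0898), immediate early (0.0504) and oxidative phosphorylation (0.282), anti-Dll4 replicates 2 and 3 ended HSC (0.0804 and 0.0556), and IgG replicate 1 ended oxidative phosphorylation (0.214). Platelet genes had a median of -0.09 (camera adjusted p = 0.769). Kit stood at 1.87 CPM against 3.84 ± 1.47 (log2 fold change -1.04, unadjusted p = 0.00548). The edgeR count of 0 stands beside 435 genes at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma-voom with weights. Without IgG replicate 1 the count was 1, Hes1 at an adjusted p of 0.0303. It was 1 without anti-Dll4 replicate 2, anti-Dll4 replicate 3 or IgG replicate 4 too, a gene other than Hes1 each time.

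In Kit+ CD45+ cells, platelet genes rose under anti-Dll4 from low levels. F2rl2 was the only gene past the threshold in edgeR, at 33.9 ± 14.2 CPM against 6.02 ± 3.12 under IgG (log2 fold change 2.51, SE 0.37, adjusted p = 0.0093). It was higher in each anti-Dll4 library than in any IgG library. Of the 23 megakaryocyte and platelet genes 20 had higher values (median 0.96), and 1 passed over all genes and 11 rose adjusted over the list alone. Camera gave the list an adjusted p = 1.08e-25, and adjusted p = 0.0118 with an estimated correlation, while fry gave 0.0519. Gp1bb, a subunit of the platelet receptor for von Willebrand factor, stood at 18.6 ± 12.4 CPM against 3.22 ± 2.89. Itgb3, the partner of Itga2b in the fibrinogen receptor, stood at 18 ± 2.61 against 8.52 ± 2.46. These levels are far below those of Kit- CD41+ CD45- cells, where F2rl2 stood at 2980 ± 245 CPM. Erythroid genes had a median of 0.57, with 15 higher and 7 lower and 2 past adjusted over the list alone (camera adjusted p = 3.91e-08, and adjusted p = 0.859 with an estimated correlation). IgG replicate 1 stood apart with low scores for both lists, erythroid 0.33 against 1.7 to 1.84 in the other 3 and megakaryocyte 2.67 against 3.49 to 3.63. Without it the erythroid median was 0.24 and the platelet one 0.76, and without anti-Dll4 replicate 1 the erythroid median was 0.31. Hemgn, an erythroid nuclear protein, stood at 2.72 ± 0.769 against 0.563 ± 0.615 CPM, while the globin share was 0.0148 ± 0.00604% against 0.015 ± 0.0061%. Hes1 stood at 49.1 ± 5.13 CPM against 81.5 ± 16.1 (log2 fold change -0.73, SE 0.29, unadjusted p = 0.0195), lower in each anti-Dll4 library than in any IgG library. The share of mitochondrial transcripts was higher too, at 0.901 ± 0.149% against 0.724 ± 0.0783% (exact permutation p = 0.0286, the smallest possible; adjusted 0.428), and this share can also move with the quality of the RNA. It was higher in each anti-Dll4 library than in any IgG library. The other 23 lists had camera adjusted p of 0.0709 or more, pan-endothelium 0.692 and Notch targets 0.793 among them. DESeq2 called 14 genes, 12 of them higher. An unadjusted p under 0.05 was found for 453 genes, fewer than the 781 that would be 5% of those tested. The F2rl2 call ended without anti-Dll4 replicate 4 (0.0675), without a low-count filter (0.0703) and with the test against a fold of 1.5 (0.0564). It also ended with the set as a random effect (0.425), in a fit of these 8 libraries alone (1), and without replicate 2, 3 or 4 of every group (0.28, 0.604 and 0.927). Its fold change lay between 2.17 and 2.75 over all alternatives.

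**Figure D3:**
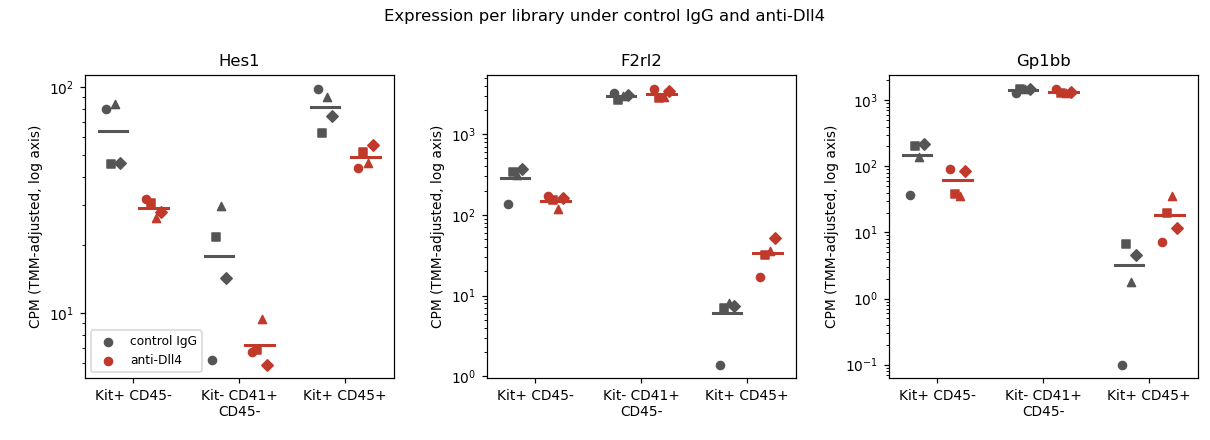
Levels (TMM-scaled CPM, log axis) of Hes1, F2rl2 and Gp1bb in each library by population; grey IgG, red anti-Dll4, symbols the replicate numbers and bars the group means. In Kit+ CD45+ cells F2rl2 is 1.4 to 8.22 CPM under IgG and 17 to 51.7 under anti-Dll4, and Hes1 is lower under anti-Dll4 in all 3 populations apart from the overlap at IgG replicate 1 of Kit- CD41+ CD45- cells.

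Averaged over the 3 populations, the anti-Dll4 effect with the smallest p was that on Hes1, with a log2 fold change of -1.06 (SE 0.17, adjusted p = 0.0522). Enpp2, which makes lysophosphatidic acid (-2.08, SE 0.39), and the transcription factor Nfib (-0.78, SE 0.16) also had small p among lower genes. Hemgn (1.16, SE 0.26) and the globin Hbb-bs (1.16, SE 0.28) were among the higher ones, and none of the 4 passed. Notch targets were lower for 14 of 17 (median -0.39, 1 adjusted over the list alone; camera adjusted p = 0.00431, and adjusted p = 0.137 with an estimated correlation), and arterial genes for 19 of 22 (median -0.53, 0 adjusted over the list alone; adjusted p = 0.137 with an estimated correlation). So were pan-endothelial genes for 27 of 28 (median -0.49, 6 adjusted over the list alone; adjusted p = 0.173 with an estimated correlation). The score differences behind these 3 averages were largest in Kit+ CD45- cells. In Kit+ CD45-, Kit- CD41+ CD45- and Kit+ CD45+ cells they were -0.68, -0.11 and -0.02 for Notch targets. They were -0.9, -0.24 and -0.16 for arterial and -0.79, -0.35 and -0.06 for pan-endothelial genes. Erythroid genes had higher values for 23 of 24 (median 0.5, 13 adjusted over the list alone; adjusted p = 0.137 with an estimated correlation). TGF-beta, adhesion and immediate early genes were lower and oxidative phosphorylation genes higher by camera, with adjusted p from 0.137 to 0.369 with an estimated correlation. The edgeR count of 0 stands beside 1311 genes at an unadjusted p under 0.05 (806 lower), 31 by DESeq2, Hes1 among them, and 0 by limma-voom with weights. Hes1 passed without Kit- CD41+ CD45- IgG replicate 1 (adjusted p = 0.000237) and without Kit+ CD45- IgG replicate 2 (0.0411) or 4 (0.0428).

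The last comparison asked whether the 3 populations answered anti-Dll4 differently, and 4 genes passed, platelet genes among them. F2rl2 (adjusted p = 0.0246) had a log2 fold change of -0.95 in Kit+ CD45- cells, 0.10 in Kit- CD41+ CD45- cells and 2.51 in Kit+ CD45+ cells. Gp6 (0.0486) stood at 2.91 against 17 CPM in the 1st, 155 against 157 in the 2nd and 1.49 ± 1.07 against 0.0762 ± 0.152 in the 3rd, where IgG had 4 counts in all. Cacna2d3, a calcium channel subunit (chromosome 14, 28904943 to 29721864, ENSMUSG00000021991.8; 0.0486), stood at 14.9 ± 4.35 against 10 ± 3.14, 4.09 ± 0.925 against 1.1 ± 0.608, and 0 against 0.452 ± 0.343 CPM. The 4th call, 4931440F15Rik (0.0486), is outside the naming rule and was chosen after its values were seen. It stood at 1.39 against 5.99, 37.9 against 36.5 and 0.252 against 0.019 CPM. As a list, platelet genes were lower by a median of 2.03 log2 units in the effect in Kit+ CD45- cells than in Kit+ CD45+ cells, for 23 of 23 members, 17 of them adjusted over the list alone (camera adjusted p = 1.07e-37, and adjusted p = 0.00222 with an estimated correlation). Hes1 did not pass this test. Pan-endothelial genes had a lower effect in Kit+ CD45- cells than in Kit+ CD45+ cells by camera (2.09e-06), with an adjusted p = 0.275 with an estimated correlation. DESeq2 called 25 genes, limma-voom with weights 2, and 631 had an unadjusted p under 0.05. With the set as a random effect the count was 0, with F2rl2 and Cacna2d3 at an adjusted p of 0.0738. Of 40 alternative fits F2rl2 kept its call in 24 and Gp6 in 10. The count was 7 without Kit+ CD45- IgG replicate 1, and 0 without any 1 of the other 7 Kit+ CD45- libraries, Kit+ CD45+ IgG replicate 4 or Kit+ CD45+ anti-Dll4 replicate 2, 3 or 4. It was 1 or 2 without any 1 of the 8 Kit- CD41+ CD45- libraries or Kit+ CD45+ IgG replicate 1 or 3.

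**Figure D4:**
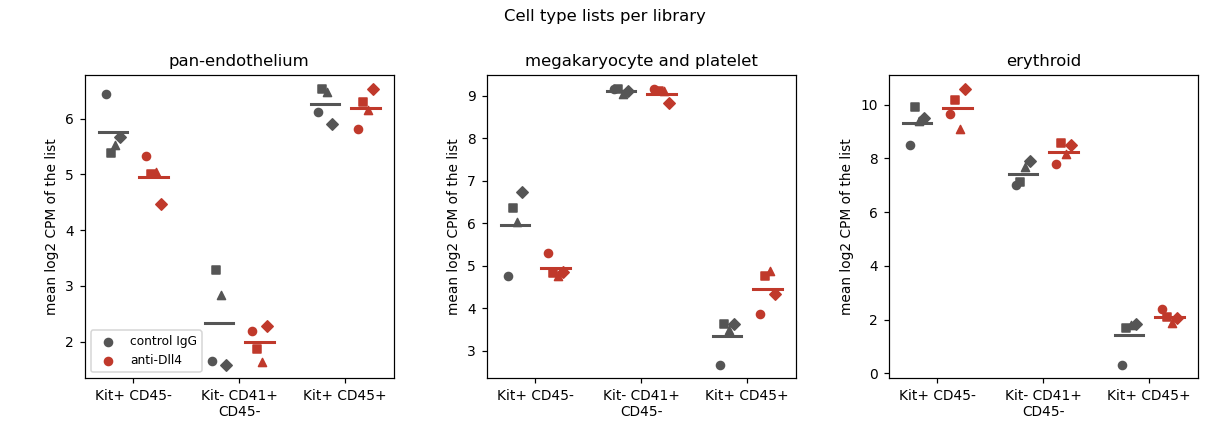
List scores (mean log2 CPM of the list's genes, y axis) per library for pan-endothelium, megakaryocyte and platelet, and erythroid genes, by population; grey IgG, red anti-Dll4, bars the group means. The pan-endothelium score in Kit+ CD45- cells was 5.75 ± 0.47 under IgG and 4.97 ± 0.36 under anti-Dll4, and the megakaryocyte score in Kit+ CD45+ cells 3.35 ± 0.46 and 4.46 ± 0.46 (both exact permutation p = 0.0286, the smallest possible; adjusted 0.238 and 0.357). The megakaryocyte score in Kit+ CD45- cells was 5.96 ± 0.86 and 4.94 ± 0.26 (exact permutation p = 0.114, adjusted 0.259).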

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

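The tests of explanations in this part were chosen only after the result was seen, apart from 2 rank correlations over platelet genes and the test of Hes1 with globin as a covariate, which were set before their outcome was known. The splits of the libraries into other groups were also chosen after the counts were seen.

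In 33 of 555 groups of 4 libraries, 1 library lay further from the other 3 than the 95% critical value of Dixon's test allows. Chance marks about 1 in 20 groups, here 27.8, so most single entries below call for no explanation. Of the 33, 9 were in Kit+ CD45- IgG replicate 1. CPM in this paragraph and the next are not scaled by TMM. In that library Efnb2 was 32.5 CPM (9.4 to 11.8 in the other 3), Cdh5 51.6 (21.1 to 22.9), Flt1 276 (95.7 to 125), Esam 268 (80.7 to 106), Dll4 25.2 (6.19 to 8.36), Igfbp3 297 (82.1 to 97.3), Sox18 123 (39.7 to 48.6) and Rnf130 85 (53.5 to 54.6). The adhesion score was 4.72 (4.26 to 4.32).

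In the other Kit+ CD45- libraries, Gsn was 28.2 CPM in IgG replicate 4 (16.2 to 17.7), and Pkhd1l1 11.9 in anti-Dll4 replicate 1 (17.1 to 17.9). In anti-Dll4 replicate 4, where globin took 49.3% of the counts, Cnn2 was 61.6 (145 to 159), Flt1 25.2 (70.9 to 77.2) and Clec1b 36 (83.9 to 86.4). Among Kit- CD41+ CD45- libraries, Tspan33 was 12.9 in IgG replicate 1 (18.8 to 19.7), Hspa4l 62.4 in IgG replicate 2 (42.9 to 45) and 25.9 in anti-Dll4 replicate 4 (47.1 to 50.4), and Hsd3b6 89.2 in IgG replicate 4 (37.7 to 44.3). The p53 score was 3.73 in IgG replicate 4 (4.13 to 4.21). In anti-Dll4 replicate 4 the megakaryocyte score was 8.84 (9.11 to 9.15) and the granulocyte-monocyte score 0.32 (-0.08 to -0.03). In Kit+ CD45+ IgG replicate 1 the erythroid score was 0.33 (1.7 to 1.84), the megakaryocyte score 2.67 (3.49 to 3.63), Stambpl1 20.1 (31.8 to 33.2) and Capg 276 (358 to 360). In Kit+ CD45+ IgG replicate 4, Notch4 was 3.29 (6.23 to 6.53) and Pecam1 213 (343 to 363). In Kit+ CD45+ anti-Dll4 replicate 1, Esam was 114 (289 to 324), Tspan33 3.57 (7.22 to 7.59), Flt4 11.6 (23.2 to 25), Ilk 225 (314 to 321) and Nrp1 30.8 (53.8 to 56). In anti-Dll4 replicate 3, Mki67 was 93.6 (74 to 77.2).

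The effect of anti-Dll4 differed between the 3 populations for F2rl2 (adjusted p = 0.0246), Gp6, Cacna2d3 and 4931440F15Rik (each 0.0486). Over the alternatives these adjusted p ran from 1.41e-07 to 1 for F2rl2, 5.23e-06 to 1 for Gp6, 8.75e-06 to 1 for Cacna2d3 and 2.49e-08 to 1 for 4931440F15Rik. As lists, camera at the preset correlation placed the effect in Kit+ CD45- cells below that in Kit- CD41+ CD45- cells for megakaryocyte (3.35e-11), NF-kB (0.00299), venous (0.02), adhesion (0.0332), epithelium (0.0401), Notch pathway (0.0438) and pan-endothelium genes (0.0456). Oxidative phosphorylation lay above (0.0332). With an estimated correlation these 8 had adjusted p from 0.274 to 0.73. Against Kit+ CD45+ cells, the effect in Kit+ CD45- cells was below for megakaryocyte (1.07e-37), pan-endothelium (2.09e-06), adhesion (7.79e-06), HSC (5.46e-05), TGF-beta, mesenchyme and arterial (each 0.00451), Notch target (0.011), NF-kB (0.0116) and venous genes (0.0161). It was above for G2/M (5.46e-05) and oxidative phosphorylation (0.00451). The megakaryocyte difference had an adjusted p of 0.00222 with an estimated correlation and 0.00267 by fry, and the other 11 had 0.104 to 0.497. The effect in Kit- CD41+ CD45- cells lay below that in Kit+ CD45+ cells for megakaryocyte (5.03e-17), HSC (0.00266), pan-endothelium (0.0183) and adhesion genes (0.0406), and above for G2/M (0.0203). With an estimated correlation these 5 had 0.0633 to 0.768.

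Endothelial genes were lower under anti-Dll4 in Kit+ CD45- cells, with a pan-endothelium median of -0.86 (camera adjusted p = 2.99e-10, and adjusted p = 0.0991 with an estimated correlation). A single library does not account for all of it: the median closest to 0 over the 8 fits without 1 library was -0.47, without IgG replicate 1, and the score difference was then -0.56 (SE 0.2). A larger share of red cells stays open, since the median was -0.43 with globin level as a covariate (camera adjusted p = 4.38e-05), and a covariate that differs between the antibodies removes part of any true effect. A general loss of RNA from cells other than red ones cannot be told apart from it either: the germ cell score rose against the pan-endothelium score by 0.62, but with an SE of 0.9 (exact permutation p = 0.543). A response to the antibody may explain the rest, as may a smaller share of endothelial cells in the sort, and neither was tested here.

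Platelet genes were lower under anti-Dll4 in Kit+ CD45- cells and higher in Kit+ CD45+ cells by camera, with adjusted p = 0.0991 and 0.0118 with an estimated correlation. In Kit+ CD45- cells the list score did not part the antibodies (exact permutation p = 0.114, adjusted 0.259), as IgG replicate 1 was as low as the lowest anti-Dll4 library. The rise in Kit+ CD45+ cells is not that of cells from the whole Kit- CD41+ CD45- gate: its median was 1.37% of the level there, which would bring 909 CPM of globin, and globin moved by -1.8 CPM (SE 42.9). Megakaryocytes or platelets alone remain a candidate explanation for part of the rise, since the rise per gene followed the Kit- CD41+ CD45- level with a Spearman rho of 0.8 over 23 members (permutation p = 2e-05). A single share of such cells does not account for all members: the rise was 36% of that level for Selp and 34.3% for Slc18a2, and Vwf, Mmrn1 and Serpine2 had lower values (-1.28, -2.56 and -2.41%). The fall in Kit+ CD45- cells, with a median of 5.96% of that level, followed it with a rho of 0.92 (permutation p = 1e-05, the smallest the permutations can give). A change of the platelet programme in proportion within the sorted cells would give such values too, and the sort by CD45 and Kit does not exclude platelets attached to other cells.

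Hes1 was lower under anti-Dll4 in all 3 populations, by a mean of -0.96 in log2 CPM (exact permutation p = 0.0286 with the 3 libraries of a set moved together, the smallest that 8 sets can give). On average Hes1 fell against the pan-endothelium score by a further -0.56 (exact permutation p over the sets = 0.0286), which argues against fewer endothelial cells as the whole of it. It does not exclude them, since the score can move less than the fold changes of low genes. In Kit- CD41+ CD45- cells the score moved by -0.35, where the list's median log2 fold change was -0.52. Against the immediate early score Hes1 fell by -0.73 (exact permutation p over the sets = 0.0286). That score moved by -0.36 in Kit+ CD45-, -0.25 in Kit- CD41+ CD45- and -0.08 in Kit+ CD45+ cells. A single gene can move more than the mean of a list, so this does not decide on a weaker dissociation response. With globin as a covariate the averaged fold change was -1.12 (unadjusted p = 3.31e-05), which argues against more red cells, while its adjusted p was 0.292. Over the alternatives the adjusted p ran from 7.02e-05 to 1, and it was 0.896 with the set as a random effect. By population, the excess over the endothelial score was -0.28 of -1.07 in Kit+ CD45- cells (exact permutation p = 0.429), so that fewer endothelial cells could account for most of it there. It was -0.75 of -1.1 in Kit- CD41+ CD45- cells (exact permutation p = 0.143) and -0.65 of -0.71 in Kit+ CD45+ cells (exact permutation p = 0.0571), and neither p decides it. The pan-endothelium score itself moved by -0.06 in Kit+ CD45+ cells. Less Notch signalling after the block of Dll4, which the design names, stays open. The score of the Notch target list, which holds Hes1, moved by -0.68 in Kit+ CD45- cells (exact permutation p = 0.114). It moved by -0.11 in Kit- CD41+ CD45- cells (exact permutation p = 0.6) and by -0.02 in Kit+ CD45+ cells (exact permutation p = 0.8). In those last populations the list as a whole showed no fall like that of Hes1. Notch signalling itself was not measured.

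A count of 0 is reached by every split of the libraries, so for the 3 counts of 0 under anti-Dll4 the number of splits says nothing about chance. In Kit+ CD45- cells these were 35 of 35 splits. The highest other, 195, came with IgG replicates 1, 3 and 4 and anti-Dll4 replicate 3 on 1 side, which points to a structure of the samples other than the antibody. These are the 4 libraries with the lowest globin share (16.85 to 29.8%, against 33.7 to 49.3% in the other 4), the measure left open above for endothelial genes. They also had more of some germ cell transcripts, such as Pou5f1 (10.9 to 21.8 CPM, against 0.115 to 6.3), Dppa3 (105 to 200, against 19.5 to 88.7) and Lin28a (2.79 to 5.05, against 0.107 to 0.523). Rhox6, Rhox9, Nanog, Alpl, Prdm14, Nanos3 and Prdm1 overlapped between the sides, with Rhox9 at 31.5 to 71.3 CPM against 3.98 to 54.7. In Kit- CD41+ CD45- cells they were 35 of 35 (highest other 4). For the average, with the 3 libraries of a set moved together, they were 35 of 35. The highest other, 565, came with sets 1, 3, 4 and 6 on 1 side, which again points to a structure other than the antibody, and what it is was not tested. At an unadjusted p under 0.05, chance cannot be excluded: 8 of 35 splits gave at least the real 1733 in Kit+ CD45- cells (highest other 3526), 19 of 35 the 435 in Kit- CD41+ CD45- cells (697), 29 of 35 the 453 in Kit+ CD45+ cells (1151) and 10 of 35 the 1311 for the average (3450). Nor can it be for the count of 1 in Kit+ CD45+ cells (4 of 35 splits, highest other 1).

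For the difference between populations, only the real split of the 35 of the sets gave as many as 4 genes (highest other 1). That is the smallest share that 35 splits can give. It was not adjusted over the other counts examined, so chance is not excluded. At an unadjusted p under 0.05, 8 of the 35 gave at least the real 631 (highest other 1126). With the libraries of each population moved apart from the others, 2 of 100 splits gave at least 4 (highest other 560) and 55 of 100 at least 631 (highest other 3282). The 4 calls also ended in limma-voom with the set as a random effect (F2rl2 and Cacna2d3 at 0.0738), a fit that changes the tool as well.

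For lists, as many were called in 3 of 35 splits in Kit+ CD45- cells (14, highest other 17), 7 of 35 in Kit- CD41+ CD45- cells (8, highest other 12), 34 of 35 in Kit+ CD45+ cells (2, highest other 8) and 6 of 35 for the average (8, highest other 13), so chance cannot be excluded for these counts. The median over the other splits was 7, 4, 5 and 5 lists. For the 3 pairs of populations, only the real split of 35 gave as many genes: 4357 (highest other 3), 2998 (417) and 5815 (79). That is the smallest share that 35 splits can give. Every other split mixes the populations and so puts their difference into the spread, which lowers its count. The splits therefore add little to the tests of single genes.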

How the results depend on the processing

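Tests with globin genes removed, with globin covariates and without set 1 or set 2 were chosen after seeing the data. Of 3323 refits of genes named here, 3142 kept their side of the threshold, 125 lost a call, 56 gained it and 0 turned direction. Of 1553 refits of called lists, 1382 kept the call, 170 lost it and 1 turned, oxidative phosphorylation in Kit- CD41+ CD45- cells with globin covariates (adjusted p = 0.951, over alternatives 0.00322 to 0.951). All 24 refits of the sort markers kept theirs.

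Counts of genes under anti-Dll4 were highest by DESeq2. In Kit+ CD45- cells the count of 0 was 75 by DESeq2, 3 with at least 10 counts in 4 libraries of a group, 14 with globin covariates, 18 without set 2, 19 without set 1, 0 to 23 without 1 library and 0 to 67 without 1 replicate number. In Kit- CD41+ CD45- cells the 0 was 2 by DESeq2, 1 with no filter, with the replicate block or without set 1, and 0 to 1 without 1 library or replicate number. In Kit+ CD45+ cells the 1 was 14 by DESeq2, 2 with globin covariates, 0 with no filter, the set as a random effect, the 1.5-fold test or only the compared groups, and 0 to 1 on leaving out libraries. For the average the 0 was 31 by DESeq2, 1 with no filter, the stricter filter or without set 1, 0 to 1 without 1 library and 0 to 2 without 1 replicate number. For the difference between populations the 4 was 25 by DESeq2, 2 by limma-voom with weights, 0 with no filter or the set as a random effect, 1 with the replicate block, 9 with globin covariates, 2 without set 2, 0 to 7 without 1 library and 0 to 14 without 1 replicate number. The cause was not tested.

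Between populations, the 1.5-fold test, stricter by construction, called 2219, 1303 and 3437 genes for 4357, 2998 and 5815. Kit+ CD45+ against Kit+ CD45- cells gave 2315 to 3397 genes without 1 library and 1551 to 3140 without 1 replicate number, with fewer samples in each fit.

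Counts of lists fell with an estimated correlation, which was 0.035 to 0.566 for the lists called, above the preset 0.01, and so widens their error: from 14, 8, 2 and 8 to 0, 0, 1 and 0 in Kit+ CD45-, Kit- CD41+ CD45-, Kit+ CD45+ cells and the average, and from 11, 17 and 15 to 4, 6 and 9 between populations. Fry called 10, 0, 0 and 5 in the first 4, and 17, 18 and 21 between populations. In Kit- CD41+ CD45- cells globin covariates gave 5, leaving out set 2 gave 3, and leaving out libraries 2 to 11. In Kit+ CD45+ cells leaving out set 1 gave 5 and leaving out libraries 3 to 7. The cause was not tested.

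The replicate numbers give no sign of pairing IgG with anti-Dll4 libraries: correlations of deviations from the group means between libraries of the same number ran from -0.15 to 0.1. With the replicate block the lists called there were 14, 8, 2 and 8. Under IgG a replicate number is also a set number. There the correlations were -0.026 to 0.033 between Kit+ CD45- and Kit- CD41+ CD45- cells. They were 0.04 to 0.076 for Kit+ CD45+ against Kit+ CD45- cells and 0.023 to 0.11 against Kit- CD41+ CD45- cells, where 3 and 4 of 4 libraries correlated best with their own number. This is a hint of shared origin from the data, not the design. With the replicate block the 4357, 2998 and 5815 genes were 4266, 2838 and 5712, and the lists 11, 16 and 15 for 11, 17 and 15, with the HSC and progenitor call between Kit+ CD45+ and Kit+ CD45- cells ended (0.0583). In limma-voom with the set as a random effect the genes were 4851, 3560 and 6617. The tool differs there as well, so the higher counts cannot be put down to the set. Depth limits genes near 3 counts per library, and in simulated Kit+ CD45- counts edgeR found 41.8% of 2-fold changes.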

Other observations

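The hypothesis of germ cells was tested by a prediction set before its outcome was known, while its gene list and the test of the sex of the sets were chosen only after the values were seen.

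Kit+ CD45- libraries held transcripts of primordial germ cells. Under IgG and anti-Dll4, Dppa3 was 102 and 90.3 CPM before TMM scaling, Utf1 46.6 and 50.4, Dppa5a 38.5 and 26.7, Rhox9 37 and 35.5, Rhox6 29.9 and 26.6 and Pou5f1 11.1 and 7.21. Dppa3 had no counts in Kit- CD41+ CD45- cells under IgG, so its TMM-scaled level was at least 384-fold higher in Kit+ CD45- cells. The list of 15 germ cell genes was written after such levels were seen, so a test of it between populations would only restate that choice. If these genes come from 1 kind of cell, they should vary together between libraries: with groups centred, the mean pairwise correlation of the 14 tested over the 8 Kit+ CD45- libraries was 0.78, against a 95th percentile of 0.1 over 10000 random lists of like level. The random lists were matched on level alone, and no other list of cell type genes was set beside this one. The value therefore does not name the source. Primordial germ cells, which carry Kit, are a candidate source within this gate. Under anti-Dll4 in Kit+ CD45- cells the list had a median log2 fold change of 0.11, and 0 of its members passed the threshold.

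Each set of 3 libraries that share a number held transcripts of 1 sex: 1 set had Y-linked transcripts, 7 had Xist without them, and 0 had more than 50 counts of both. If each set held 2 embryos of unselected sex, the chance that all 8 are of 1 sex would be 0.00391, and lower with more embryos, which argues against sets of several embryos of unselected sex. A set from a single embryo would give this outcome and was not tested otherwise. Kit+ CD45+ anti-Dll4 replicate 3 had 15 Ddx3y counts and 0 of Eif2s3y. A share of 1.18% of replicate 1, which would bring those Ddx3y counts, would also bring 14.7 Eif2s3y counts. With 7 of 8 sets of the same sex, the sex of the embryos is not balanced between the antibodies, and the counts without set 2 are given above.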
